A study of Oryza sativa Japonica Group with 17 samples.

How the data were processed

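Total RNA of rice leaf blades was labelled with the dye Cy3 and hybridised to one-colour Agilent oligonucleotide arrays of 45151 features. The plants were of the cultivar Nipponbare and grew in a paddy field. The uppermost fully expanded leaf of the main stem was taken at 12:00 every 7 days, from 13 to 125 days after transplanting. This gave 17 stages and 17 arrays, 1 per stage. The series text names 3 replicates per stage, but 1 array per stage is deposited, and whether RNA was pooled is not given in the sources used here. The arrays sat on 5 slides in the order of the days, with days 13 to 34, 41 to 62, 69 to 90 and 97 to 118 on slides 1 to 4 and day 125 alone on slide 5. Slide and day are therefore tied together in this design.

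The deposited scanner files give signal intensity per feature, per the file headers, with background subtraction and detrending by Agilent Feature Extraction (version 10.5.1.1, per the submitters' processing notes) and no scaling between arrays. The deposited series matrix gives log2 values, in which the authors subtracted 1 constant per array so that the 75th percentile of the array lies at 0. For each feature the difference between the matrix value and log2 of the scanner file's processed signal was checked and is constant within each array.

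Values were computed from the processed signals as log2 minus the 75th percentile of the array's non-control features. Of the 43734 non-control features, 42124 carry a gene identifier. Spots marked as non-uniform or as outliers among their repeats were left out, and repeated spots of 1 probe were averaged. For each gene the probe with the highest mean stood for the gene, which matters for the 7801 of 29690 genes with more than 1 probe. A gene was tested if its probe was well above background, by the scanner software's own mark, on at least 5 arrays, which held for 22807 genes (76.8%) and left out 6883. The 75th percentile of the signal lay between 2304 and 4466 intensity units per array, and 72.0% to 76.9% of non-control features per array were well above background. No feature was saturated. With arrays there is no count behind a value, and the number of arrays limits the precision.

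Tests were made with limma 3.58.1 in R 4.3.3. Change over the season was tested with a natural spline of 4 degrees of freedom in day and a moderated F test with 12 residual degrees of freedom. For window contrasts the days were grouped as early (13 to 48, n = 6), middle (55 to 83, n = 5) and late (90 to 125, n = 6), and late minus early, middle minus early and late minus middle were tested by the moderated statistic of limma with 14 residual degrees of freedom. The stages of a window stand in for replicates, so the error contains change within the window. P-values were adjusted by Benjamini-Hochberg over all 22807 genes, with a threshold of 0.05, and all tests are two-sided. Weekly steps, the differences between neighbouring stages, rest on 1 array each and carry no test per gene. The number of genes moving at least 2-fold was compared between the 4 steps that cross slides and the 12 that do not by an exact permutation test.

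Gene lists were written before the data were examined, as were the windows, the tests, the filters, the alternatives below and the rule for named genes. There were 27 lists: photosystem and light-harvesting proteins, Calvin cycle enzymes, photorespiration enzymes, chlorophyll synthesis, chlorophyll breakdown and leaf senescence, nitrogen assimilation and remobilisation, flowering time and photoperiod, circadian clock, sucrose and starch metabolism, phosphate starvation, abscisic acid and dehydration, cold response, defence and jasmonate, diterpenoid phytoalexin synthesis, cell division, cellulose synthesis and lignin, gibberellin, cytokinin, heat shock proteins, cytosolic ribosomal proteins, plastid ribosomal proteins, histones, reference genes, and markers of root, seed storage, panicle and floral organs, and shoot meristem. Members were found by gene identifier, or by described product for both ribosomal protein lists and the histones. A member was left out where the array describes its identifier as a different protein, which removed 7. Gene symbols are those of the lists, and identifiers and descriptions are those of the deposited files. The 23 lists with at least 3 tested members were tested with camera at its preset correlation of 0.01. Camera was also run with an estimated correlation, with which no list passed in any contrast, and fry as an alternative. For each list the count of members past the threshold is also given adjusted over the list alone.

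The rule for named genes took, per window contrast, the 5 largest rises and the 5 largest falls by fitted difference of at least 2-fold past the threshold with a described product, for the season the 5 genes with the smallest p and a described product, and from each list the 4 members with the smallest p. Members of the flowering and clock lists, the markers of other tissues and the reference genes could be named in any number. Some genes that the rule takes are not reported here, and counts include them.

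A difference is given as a bound where the probe was not well above background on every array of a window. The bound is the mean of the higher window minus the mean of the lower window, with each array of the lower window that was not well above background raised to the lowest well-above-background value of that array. Such differences are written as at least N-fold, with the adjusted p of the fit.

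The tests were run on simulated data with each gene's own residual spread. Of 100 genes changed 2-fold, 63% were recovered for late minus early, 52% for middle minus early, 58% for late minus middle and 25% for the season. Of 100 genes changed 4-fold, 85%, 89%, 90% and 67% were recovered in the same order. There were 8, 11, 5 and 9 false calls among 22807 genes. Of 22 simulated lists of 20 genes, camera called the 1 that had been moved and 0 others. The simulated genes were independent of each other, and so were the simulated arrays of each gene. In the data neighbouring weeks are alike and the slides follow the days. The false calls therefore do not measure the error of the tests on the real arrays. For the season the simulated change grew in a straight line and reached its full size only on day 125. In the data the estimated correlation was 0.701 within the photosystem list and 0.862 within the cytosolic ribosomal protein list. The simulation therefore does not show how often camera calls unmoved lists whose members move together.

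Alternatives tried were quantile normalization, scaling by the median, normexp background correction (offset 50), the series matrix values, no filter, only probes well above background on all 17 arrays, a floor under dim values, every probe by itself, outlier spots kept, slide as a fixed or random block, splines of 3 and 5 degrees of freedom, a straight line in day with and without slide, an F test over the windows, windows moved 1 week earlier or later, steps of 1.5-fold and 4-fold, and leaving out each array in turn. Cyclic loess scaling, and the fits without days 20 and 76 or without days 76 and 83, were added after the data had been seen. Regroupings of the arrays were 100 random draws. Probes named after microRNAs and 15 gene families by description were looked at only afterwards.

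Genome positions are not given, because the gene table used here as reference matched 0 of the array's identifiers. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 was used to read the files and draw the plots.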

Results

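Gene expression in rice leaf blades was followed through 1 growing season with 17 arrays, 1 for each sampling every 7 days from 13 to 125 days after transplanting. The comparisons are change with day, and differences between the early (days 13 to 48, n = 6 arrays), middle (days 55 to 83, n = 5) and late (days 90 to 125, n = 6) parts of the season. Values are log2 of the signal relative to the 75th percentile of each array. Each stage has a single array, so spread is given between the stages of a window. The 75th percentile lay between 2304 and 4466 intensity units, and 72% to 76.9% of features per array were well above background.

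Most of the leaf transcriptome moved with the season. The floral identity factor OsMADS14 (Os03g0752800), which acts downstream of florigen, gave the smallest p among genes with a described product (F = 228, adjusted p = 8.03e-09). Next among these came a remorin (Os10g0325400), a plasma membrane protein family, which had its fitted peak on day 62 and fell afterwards. A NAM-domain factor (Os07g0566500) and an aldo/keto reductase (Os10g0114300) had their fitted peaks on day 125. The copalyl diphosphate synthase gene CPS1 (Os02g0278700), which starts gibberellin synthesis, was highest on day 13. Of 22807 genes, 15794 (69.3%) changed over the season, 12359 of them with a fitted range of at least 2-fold and 1722 of at least 16-fold. The fitted peak lay on day 13 for 3847 of the 2-fold genes (31.1%) and on day 125 for 3090 (25%). A straight line in day rose for 5664 genes and fell for 5990. With slide as a fixed block, which removes any difference between slides along with most of the difference between days, 1371 genes passed.

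Neighbouring weeks differed by very unequal amounts. From day 13 to day 20, 2738 genes rose and 2976 fell by at least 2-fold, 25.1% of those tested. The steps from day 55 to 62 (3717 genes, 16.3%), day 20 to 27 (3674), day 97 to 104 (2965) and day 83 to 90 (2756, 12.1%) followed. The steps from day 13 to 20 and from day 20 to 27, both within slide 1, share the single array of day 20. On it the medians of the cytosolic ribosomal protein list (1.13) and of the reference genes (2.82) lay below those of all other early arrays. The smallest steps were day 62 to 69 (733 genes, 3.21%) and day 118 to 125 (893), and both of these cross from 1 slide to the next. The 4 steps that cross slides moved 1447.5 genes on average and the 12 within slides 2643.9 (exact permutation p = 0.0967, 1820 choices), so no excess at slide borders was seen. Across genes, arrays 1 week apart correlated at a mean r of 0.977 (16 pairs), which dropped to 0.827 for the pair 16 weeks apart. Genes are not independent replicates in these correlations.

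**Figure D1:**
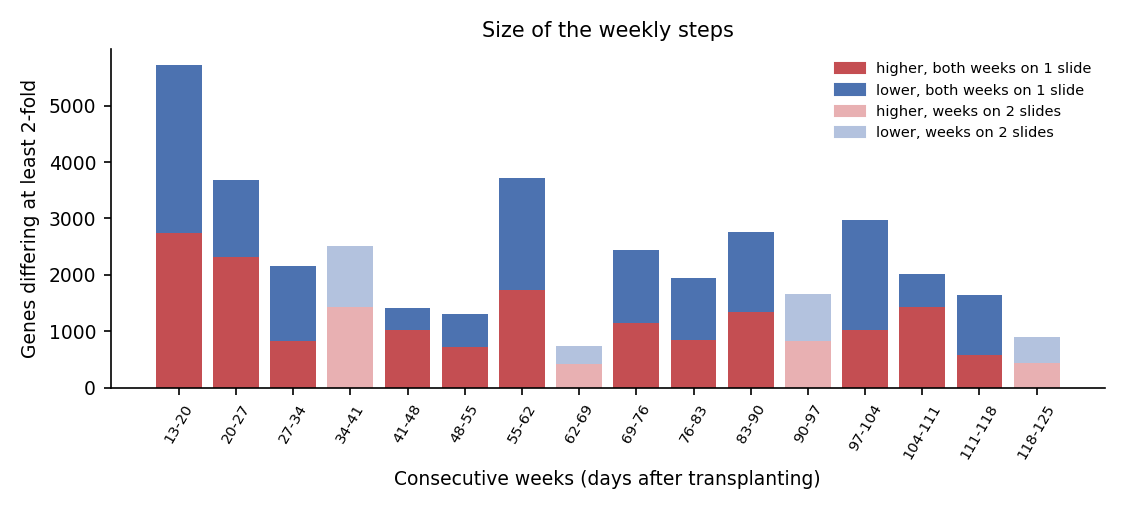
Number of genes at least 2-fold higher or lower than in the week before, for the 16 steps between neighbouring stages, with paler bars for steps whose arrays lie on different slides. The step from day 13 to 20 was the largest with 2738 genes higher and 2976 lower, and the step from day 62 to 69 the smallest with 733 in all.

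Relative to the array's 75th percentile, mRNA for photosynthesis was lower in late than in early leaves. That percentile was lowest on day 20 (2304 intensity units) and highest on day 125 (4466). Without scaling, the median change of the photosystem list in log2 signal was -0.213, so the size of the falls depends on the scaling. Of 34 photosystem and light-harvesting genes, 32 fell and 1 rose (the same when adjusted over the list alone), with a median of -0.68. Examples are the antenna protein Lhcb6 (5.53 ± 0.32, SD, n = 6, early and 3.75 ± 0.64, n = 6, late, a difference of -1.78, SE 0.25, adjusted p = 3.8e-05), the ATP synthase subunit AtpD (-1.81, SE 0.26), PsaF of photosystem I (-1.19, SE 0.17) and PsaK (-1.0, SE 0.18). Of 18 Calvin cycle genes, 17 fell and 1 rose (also when adjusted over the list alone), with a median of -0.98. The epimerase RPE (-1.12, SE 0.15), plastid phosphoglycerate kinase cpPGK (-1.39, SE 0.20) and SBPase (-1.03, SE 0.15) fell, while the transketolase gene TKL2 rose by 2.36 (SE 0.25, adjusted p = 5.5e-06). Of 12 photorespiration genes, 10 fell (10 also over the list alone) with a median of -0.48. Among them were the glycine decarboxylase subunit GDCH (-2.13, SE 0.28) and the phosphoglycolate phosphatase PGLP1 (-1.65, SE 0.22).

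Chlorophyll synthesis genes fell, and some genes of chlorophyll breakdown rose. Of 10 chlorophyll synthesis genes, 7 fell and 0 rose (7 over the list alone), with a median of -0.87. They include HEMA1 (-1.75, SE 0.31), which makes the precursor of all tetrapyrroles, the protochlorophyllide reductases PORA (-3.96, SE 0.71) and PORB (-1.57, SE 0.30), and the chlorophyllide a oxygenase CAO1 (-0.90, SE 0.17). Of 10 genes of chlorophyll breakdown and leaf senescence, 5 rose and 1 fell (6 and 2 adjusted over the list alone), but the list as a whole did not pass (median 0.74, adjusted p = 0.0947). The senescence regulator OsNAP (Os03g0327800) rose from -4.57 ± 1.22 (SD, n = 6) to -0.26 ± 1.27 (n = 6), a difference of 4.31 (SE 0.61, adjusted p = 4.46e-05). The red chlorophyll catabolite reductase gene RCCR1 was at least 7.04-fold higher (5 of 6 early arrays measured it; adjusted p = 3.43e-05), and NYC1, a chlorophyll b reductase, fell by 0.66 (SE 0.19).

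By camera with its preset correlation the photosystem (adjusted p = 6.57e-09), Calvin cycle (1.24e-05), photorespiration (0.00365) and chlorophyll synthesis lists (0.0188) passed. None of the 4 passed with a correlation estimated from the data (adjusted p = 0.676 for each with an estimated correlation). No slide holds both early and late arrays, and with slide as a fixed block the medians were -0.16 (adjusted p = 0.318) for photosystem, -0.25 (0.318) for Calvin cycle, -0.24 for photorespiration and -0.40 (0.492) for chlorophyll synthesis genes. With quantile normalization 12 photosystem genes fell (median -0.14, adjusted p = 0.0145), 11 Calvin cycle genes (-0.42, 0.00627) and 5 photorespiration genes with 1 higher (-0.06, 0.282). With cyclic loess 20 photosystem genes fell (-0.31), 14 Calvin cycle genes (-0.60) and 5 photorespiration genes (-0.16, adjusted p = 0.0877). Chlorophyll synthesis lost its call without day 13 (median -0.77, adjusted p = 0.0716).

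**Figure D2:**
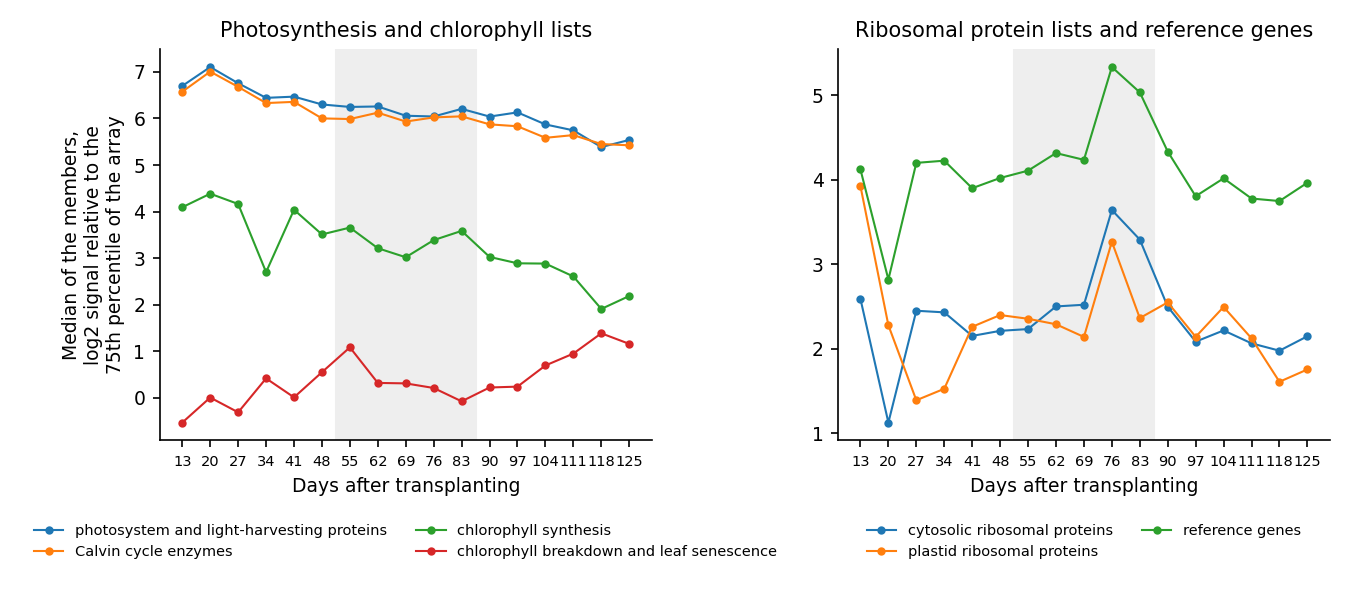
Median of each gene list on each sampling day, as log2 relative to the array's 75th percentile, with the middle window in grey. The photosystem list went from 7.11 on day 20 to 5.39 on day 118, and the cytosolic ribosomal protein list from 1.13 on day 20 to 3.64 on day 76.

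Among tested genes with a described product, OsMADS14 had the largest fitted rise from the early to the late window. It was measured on 2 of 6 early arrays and on every later one, at 1.55 ± 2.08 (SD, n = 5) in the middle and 3.79 ± 0.23 (n = 6) in the late window, at least 925-fold above early (adjusted p = 5.32e-07). The florigen gene Hd3a (Os06g0157700, at least 5.55-fold, on 0 of 6 early arrays) rose too, as did Ehd1 (at least 1.64-fold, on 0 of 6 early arrays), a B-type response regulator that induces Hd3a. OsMADS15 rose by 2.39 (SE 0.47), OsMADS18 by 0.89 (SE 0.26) and phytochrome gene PHYA by 0.91 (SE 0.17). The last 2 turned negative (-0.29 and -0.018) with slide as a fixed block. The repressor DTH8 (-2.55, SE 0.28), OsMADS50 (-2.04, SE 0.24), OsMADS56 (-1.45, SE 0.20), the pseudo-response regulator PRR37 (-1.08, SE 0.16) and Hd6 (-1.21, SE 0.21) fell. The photoperiod gene Hd1 did not pass (0.37, SE 0.41, adjusted p = 0.475). In all, 9 of 23 flowering genes rose and 7 fell (9 and 7 adjusted over the list alone), and the list as a whole did not pass (median 0.09, adjusted p = 0.681).

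Of 11 clock genes 7 were lower and 2 higher (8 and 2 adjusted over the list alone; median -0.66, adjusted p = 0.0947). PRR73 (-1.29, SE 0.20), the morning gene LHY (-1.18, SE 0.28), PRR95 (-0.96, SE 0.27) and GI (-0.61, SE 0.15), a clock protein of the photoperiod pathway, fell. All samples were taken at 12:00, so these are levels at that hour.

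**Figure D3:**
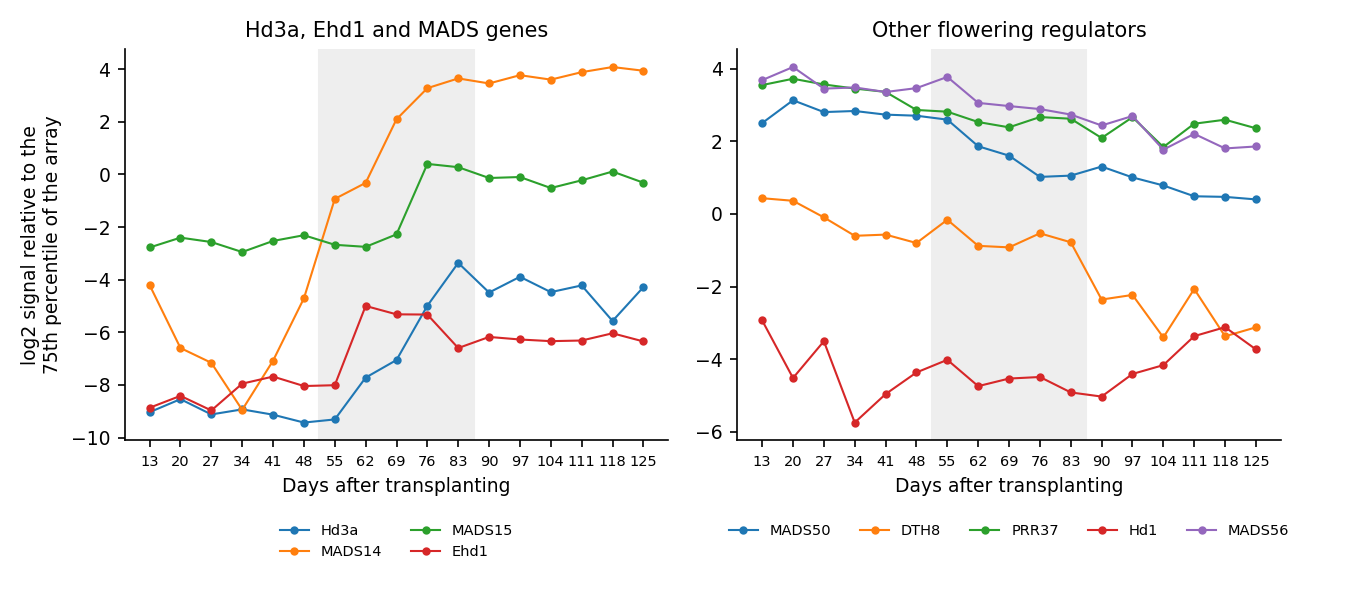
Level of 9 flowering genes on each sampling day, as log2 relative to the array's 75th percentile, with the middle window in grey. OsMADS14 was at -4.71 on day 48 and at 2.1 on day 69, while OsMADS50 went from a mean of 2.79 in the early window to 0.74 in the late one.

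Genes for diterpenoid phytoalexins, antimicrobial compounds of rice, were far higher in late leaves. Of 9 tested, 8 rose and 0 fell (8 over the list alone), with a median of 4.34, or 3.79 with members at their bounds (camera adjusted p = 1.41e-04; adjusted p = 0.637 with an estimated correlation). The synthase gene CPS4 (Os04g0178300) went from -5.03 ± 1.12 (SD, n = 6) to -0.32 ± 1.14 (n = 6), a rise of 4.71 (SE 0.59, adjusted p = 1.69e-05). The cytochrome P450 gene CYP71Z7 rose by 4.56 (SE 0.56), KSL7 was at least 44.8-fold higher (on 3 of 6 early arrays) and KSL10 at least 17.1-fold (on 0 of 6). Of 11 markers of panicle and floral organs 7 were tested, with 5 higher and 1 lower. These counts were the same over the list alone (median 1.08, or 0.72 at the bounds, camera adjusted p = 0.0798). Among the tested ones OsMADS1 was at least 18.0-fold higher (5 of 6 early arrays) and OsMADS2 at least 2.07-fold lower. Of those not tested, OsMADS7 and OsMADS8 were well above background on 1 of the 17 arrays each, and OsMADS13 and OsC6 on 0.

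Of 14 defence and jasmonate genes, 6 rose and 2 fell (also over the list alone; median 1.14, adjusted p = 0.181). The pathogenesis-related gene PR1b rose by 6.85 (SE 0.78, adjusted p = 8.04e-06), PBZ1 by 1.93 (SE 0.34) and NH1, the rice counterpart of the salicylic acid regulator NPR1, by 1.58 (SE 0.38), and PR1a was at least 8.76-fold higher (5 of 6 early arrays).

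The gibberellin list was lower in late leaves, and so were single cellulose genes, though not their list as a whole. Of 8 cellulose and lignin genes, 6 fell and 2 rose (the same over the list alone; median -2.88, adjusted p = 0.0681, or just under 0.05 without days 76 and 83). The cellulose synthases CESA4 (at least 15.3-fold lower, on 0 of 6 late arrays), which makes secondary walls, and CESA8 (-3.20, SE 0.39), and BC1, a cell wall assembly protein (at least 14.0-fold lower, on 0 of 6 late arrays), fell. The alcohol dehydrogenase gene of lignin synthesis CAD2 rose by 3.71 (SE 0.39). Of 10 gibberellin genes, 7 fell and 1 rose (the same over the list alone; median -0.94, adjusted p = 0.0197; adjusted p = 0.256 with an estimated correlation). The synthesis genes CPS1 (at least 29.3-fold lower, on 2 of 6 late arrays), GA3ox2 (at least 16.2-fold lower, on 5 of 6 late arrays), KAO (-2.13, SE 0.26) and KO2 (-1.06, SE 0.18) fell. With only the probes well above background on all 17 arrays the gibberellin list had a median of -0.68 and did not pass (adjusted p = 0.153). OSH1, a marker of the shoot meristem, fell by 1.3 (SE 0.22, adjusted p = 2.09e-04).

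**Figure D4:**
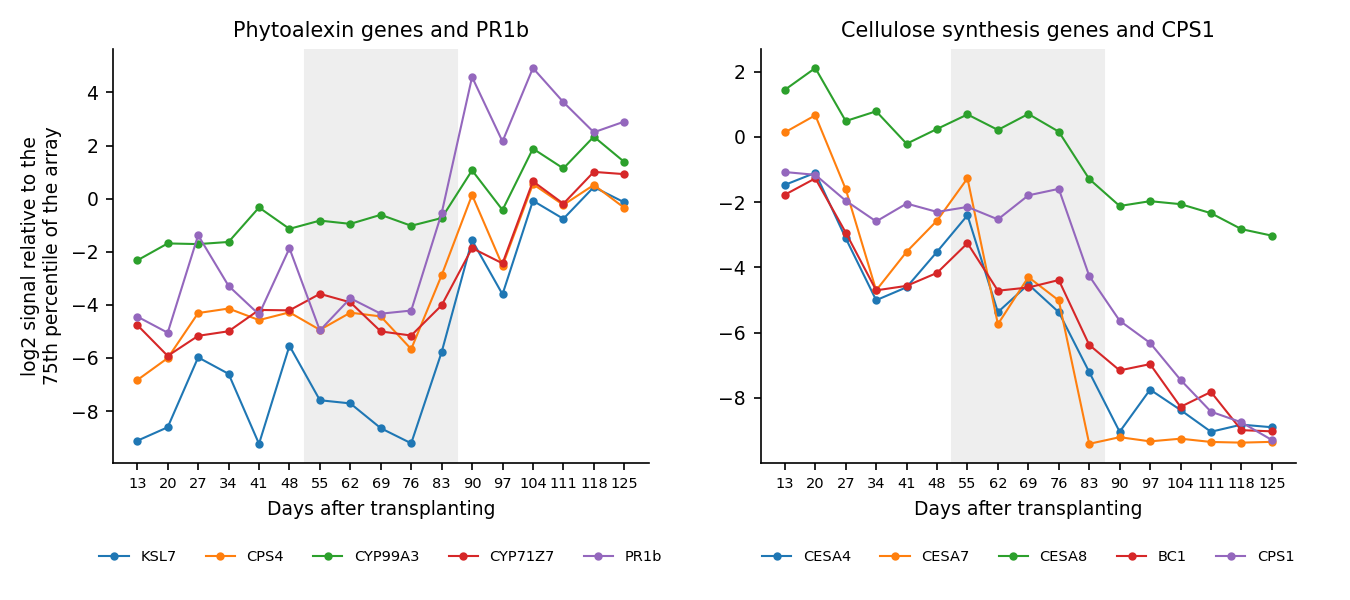
Level of 5 defence and phytoalexin genes and of 5 cell wall and gibberellin genes on each sampling day, as log2 relative to the array's 75th percentile, with the middle window in grey. PR1b went from a mean of -3.56 in the middle window to 3.45 in the late one. CPS1 went from -2.46 to -7.65, but it was well above background on 2 of 6 late arrays, so its fall is given as at least 19.2-fold.

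Other metabolic and stress lists did not pass as wholes, though single members did. Of 14 nitrogen genes, 3 rose and 6 fell (the same over the list alone; median -0.24, adjusted p = 0.681). The plastid glutamine synthetase gene GS2 fell by 1.04 (SE 0.15), the cytosolic GS1;1 rose by 1.12 (SE 0.23), and the glutamate dehydrogenase gene GDH2 rose by 0.65 (SE 0.15). Of 20 sucrose and starch genes, 3 rose and 8 fell (the same over the list alone; median -0.59, adjusted p = 0.269), including the ADP-glucose pyrophosphorylase subunit AGPL3 (-1.66, SE 0.25), the leaf starch synthase GBSSII (-1.58, SE 0.30) and the sucrose transporter SUT2 (-0.98, SE 0.17). Of 7 phosphate starvation genes, 1 rose and 4 fell (the same over the list alone; median -1.39, adjusted p = 0.273). PHO2, which restrains phosphate uptake, rose by 1.76 (SE 0.32), and the sulfolipid synthase SQD2 fell by 1.71 (SE 0.32).

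Of 9 abscisic acid and dehydration genes, 1 rose and 1 fell (the same over the list alone; median -0.22, adjusted p = 0.681). The salt-induced lectin gene SalT was at least 48.0-fold lower (4 of 6 late arrays), and the factor bZIP23 rose by 0.81 (SE 0.25). Of 3 cold response genes DREB1A fell by 2.57 (SE 0.37) and the others did not pass (1 lower over the list alone; median -0.06, or 0.00431 with quantile normalization, adjusted p = 0.619). Of 7 cytokinin genes, the cytokinin oxidase CKX2 was at least 8.21-fold higher and the response regulator RR1 fell by 1.91 (SE 0.54). These 2 were also the ones past the threshold over the list alone, and the list's median of -0.29 and mean of 0.07 differ in sign (adjusted p = 0.961). Of 5 cell division genes, 1 rose and 2 fell (the same over the list alone; median -0.85, or -0.08 at the bounds, adjusted p = 0.369). The cyclin CYCB2;1 was at least 2.37-fold lower (on 0 of 6 late arrays) and the kinase CDKB2;1 at least 4.41-fold lower (2 of 6). Of 2 heat shock genes, too few for a list test, the chaperone HSP101 rose by 2.72 (SE 0.54) and HsfA2a did not pass, also over the list alone.

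The ribosomal protein lists had medians near 0 in this contrast. Of 149 cytosolic ribosomal protein genes, 5 rose and 3 fell (1 and 2 over the list alone; median -0.03, adjusted p = 0.961), and of 17 plastid ones 0 rose and 1 fell (0 and 0 over the list alone; median -0.00219, adjusted p = 0.961). Both medians turned positive with quantile normalization (0.08 and 0.12), and camera pointed up although medians and means were negative. Of 46 histone genes, 16 rose and 6 fell (19 and 6 over the list alone; median 0.45, adjusted p = 0.0798). The reference genes UBQ5, UBQ10, eEF1a and ACT1 were not called in any contrast, also over the list alone (late minus early median of the list 0.06, adjusted p = 0.766). This depends on the scaling, since in late minus early 2 of the 5 members of that list were called higher with quantile normalization (median 0.28), 1 with cyclic loess and 1 with median scaling. The root marker Lsi1 (-0.09, SE 0.39) and the seed storage gene GluA2 (-0.18, SE 0.18) were not called in any contrast over all genes, while Lsi1, the single tested member of its list, passed over the list alone in middle minus early (-0.88).

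Across all genes, 5434 were higher and 6007 lower in the late than in the early window (50.2% of those tested), of which 2527 and 3219 differed at least 2-fold. Which direction held more genes depended on the scaling, with 6162 higher and 5168 lower with quantile normalization and 5982 and 5452 with median scaling. Among the largest rises beside OsMADS14 were a VQ-domain gene (Os07g0687400, at least 234-fold, on 0 of 6 early arrays), a cytochrome P450 (Os01g0543600, at least 361-fold, 2 of 6) and a protein kinase (Os07g0131100, at least 147-fold, 2 of 6). Large falls were seen in the peroxidases Os02g0240300 (at least 321-fold, on 1 of 6 late arrays) and Os01g0294700 (at least 161-fold), a methyltransferase (Os02g0719600, at least 140-fold), a xyloglucan endotransglucosylase (Os06g0697000, at least 113-fold), an enzyme class that loosens walls, and a tumor-related protein (Os10g0552700, at least 94.1-fold), the last 4 on 0 of 6 late arrays. With slide as a fixed block limma called 7 genes higher and 34 lower (1886 at an unadjusted p under 0.05). Of 108 calls on named genes in this contrast 98 remained with each array left out in turn. A straight line in day with the slide block called 0 (3351 at an unadjusted p under 0.05).

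Several flowering genes differed between the middle and the early window, though not their list as a whole. OsMADS14 was at least 196-fold higher (adjusted p = 3.07e-04), on 2 of 6 early and 5 of 5 middle arrays, with every middle array above every early one. Ehd1 was at least 1.88-fold higher (on 0 of 6 early and 4 of 5 middle arrays), Hd3a at least 1.39-fold (0 of 6 and 2 of 5), and OsMADS18 rose by 1.45 (SE 0.27). OsMADS50 (-1.16, SE 0.25), PRR37 (-0.81, SE 0.17) and SE5 (-0.98, SE 0.21), a haem oxygenase that makes the phytochrome chromophore, fell. This makes 5 of 23 flowering genes higher and 3 lower (5 and 5 adjusted over the list alone; median 0.11, adjusted p = 0.469).

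Other large rises were a gene described as MOTHER of FT and TF1 (Os06g0498800, at least 37.8-fold, 3 of 6 early arrays) and a protein kinase (Os11g0691500, at least 35.1-fold, 4 of 6). Large falls were seen in the phenylalanine ammonia-lyases Os12g0520200 (-6.03, SE 0.93, adjusted p = 0.00532) and Os11g0708900 (at least 44.8-fold, 2 of 5 middle arrays), which open the phenylpropanoid pathway. A gene described as FLOWERING LOCUS T (Os04g0488400, at least 27.5-fold, on 5 of 6 early and 0 of 5 middle arrays), a terpene synthase (Os11g0286800, at least 26.4-fold, 1 of 5) and a clathrin adaptor (Os11g0244600, at least 25.8-fold, on 0 of 5 middle arrays) fell too.

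The photosynthesis lists were lower in the middle window with the scaling used here, but most members were not called, and the calls ended with quantile normalization. Of 34 photosystem genes 7 fell and 0 rose (26 and 0 adjusted over the list alone; median -0.41, adjusted p = 1.31e-08), for example the ferredoxin reductase LFNR2 (-0.64, SE 0.17). Of 18 Calvin cycle genes 4 fell and 0 rose (11 and 1 over the list alone; median -0.41, adjusted p = 7.3e-05), for example RPE (-0.75, SE 0.16). Of 12 photorespiration genes 4 fell and 0 rose (7 and 0 over the list alone; median -0.40, adjusted p = 0.00185), for example PGLP1 (-1.13, SE 0.23). Of 11 clock genes 3 fell and 1 rose (6 and 1 over the list alone; median -0.75, adjusted p = 0.015), with PRR73 at -0.98 (SE 0.21), PRR37 and GI lower, and ZTL2 higher by 0.53 (SE 0.13). None of these 4 lists passed with an estimated correlation (adjusted p = 0.677 for each), and none passed with quantile normalization, where the medians were -0.03 (adjusted p = 0.236), -0.04 (0.236), -0.08 (0.297) and -0.67 (0.0698), and 1 photosystem, 2 Calvin cycle and 1 photorespiration gene fell. The clock list also lost its call without days 20 and 76 (-0.47, adjusted p = 0.0659).

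The cytosolic ribosomal protein list was higher in the middle than in the early window, with 11 of 149 members past the threshold, all higher, 138 not called, 0 over the list alone, and a median of 0.68 (adjusted p = 6.03e-19; adjusted p = 0.677 with an estimated correlation). With quantile normalization 28 members were called higher and with cyclic loess 19. The median was 0.25 (adjusted p = 2.77e-08) without days 20 and 76 and 0.25 (adjusted p = 2.85e-04) without days 76 and 83. The other lists tested did not pass, and the 2 heat shock genes were too few for a list test. For all of these, the members higher and lower, the same adjusted over the list alone in brackets, and the median were as follows. For plastid and nitrogen functions they were 0 and 0 (0 and 0), -0.46, for chlorophyll synthesis, 1 and 0 (1 and 1), -0.01 with a mean of 0.10, for chlorophyll breakdown, and 0 and 0 (1 and 4), -0.27, for nitrogen genes. Sucrose and starch genes had 0 and 1 (0 and 5), -0.49 or -0.37 at the bounds, and phosphate starvation genes 1 and 1 (1 and 4), -1.35. Abscisic acid genes had 0 and 1 (0 and 1), 0.19 with a mean of -0.14, and cold response genes 0 and 1 (0 and 1), -0.23. Defence genes had 2 and 0 (2 and 0), 0.45 or 0.42 at the bounds, and phytoalexin genes 0 and 0 (0 and 0), 0.54. Cell division genes had 0 and 1 (2 and 1), 0.48 or 0.26 at the bounds, and cellulose and lignin genes 0 and 0 (0 and 0), -0.75. Gibberellin genes had 0 and 2 (0 and 2), -0.41, cytokinin genes 0 and 0 (0 and 0), -0.26, and heat shock genes 1 and 0 (1 and 0), 1.3. Plastid ribosomal proteins had 0 and 0 (0 and 0), 0.51, histones 1 and 0 (1 and 0), 0.17 (0.34 with an adjusted p of 0.00114 without days 76 and 83), and floral organ markers 2 and 1 (2 and 1), 0.00795 or 0 at the bounds. The chlorophyll breakdown median turned positive with quantile normalization (0.05), and the floral one negative with cyclic loess (-0.00323). WRKY45, a regulator of induced resistance, rose by 2.52 (SE 0.62), HSP101 by 2.0 (SE 0.56) and OsMADS1 was at least 7.09-fold higher, while KO2 fell by 1.09 (SE 0.19) and OSH1 by 0.92 (SE 0.23).

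In all, 1002 genes were higher and 1342 lower in the middle window (10.3%), of which 544 and 518 differed at least 2-fold. These counts depend on single arrays. They were 156 to 340 and 207 to 659 without day 20, 27, 62, 69, 76 or 83, 2020 and 2343 without day 48, 2369 and 2559 without day 55, 18 and 10 without days 20 and 76, and 16 and 6 without days 76 and 83. Of 53 calls on named genes 15 remained with each array left out in turn, 4 remained without days 20 and 76, among them those of OsMADS14 and the clathrin adaptor, and 3 without days 76 and 83. With slide as a fixed block limma called 0 and 0 (288 at an unadjusted p under 0.05). On slide 2 alone, which holds 2 early and 2 middle arrays, limma called 0 genes (556 at an unadjusted p under 0.05).

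Phytoalexin genes rose between the middle and the late window, and so did single defence genes. Of 9 phytoalexin genes 7 rose and 0 fell (8 and 0 adjusted over the list alone; median 3.04, or 2.89 at the bounds, adjusted p = 1.47e-05; adjusted p = 0.381 with an estimated correlation). KSL7 was at least 58.1-fold higher (1 of 5 middle arrays), KSL10 at least 18.9-fold (0 of 5), and CPS4 rose by 4.13 (SE 0.62) and CYP71Z7 by 4.02 (SE 0.59). On slide 3, which holds days 69 to 90, the list's median was 3.03 higher on day 90 than on the mean of the 3 earlier days. The median of the members lay at -2.89 on day 83, -0.79 on day 90, -2.52 on day 97 and between -0.76 and 0.44 on later days. PR1b rose by 7.01 (SE 0.82, adjusted p = 4.45e-05) and the allene oxide synthase of jasmonate synthesis, AOS2, was at least 4.91-fold higher (1 of 5 middle arrays), while WRKY62, a repressor of defence, was at least 16.3-fold lower (3 of 6 late arrays). In the defence list 4 of 14 rose and 1 fell (the same over the list alone; median -0.15, mean 0.49, adjusted p = 0.701), and with slide as a fixed block its median was 0.72 (adjusted p = 0.0325). Floral organ markers rose in 3 of 7 (3 over the list alone; median 1.0, or 0.86 at the bounds, adjusted p = 0.0497; adjusted p = 0.584 with an estimated correlation), with OsMADS3 at least 2.91-fold and OsMADS58 at least 1.82-fold higher and OsMADS4 up by 1.0 (SE 0.26).

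Some senescence genes rose and some photosynthesis genes fell further between these windows. OsNAP rose by 3.82 (SE 0.64, adjusted p = 5.88e-04), RCCR1 by 2.04 (SE 0.42) and the pheophorbide a oxygenase gene PAO by 0.91 (SE 0.23), with 4 of 10 breakdown genes higher and 0 lower (5 and 1 over the list alone; median 0.71, adjusted p = 0.0497; adjusted p = 0.584 with an estimated correlation). The call of this list ended with a floor under dim values (adjusted p = 0.053) and without days 76 and 83 (0.163). Of 34 photosystem genes 7 fell and 0 rose (the same over the list alone; median -0.31, adjusted p = 3.7e-04; adjusted p = 0.744 with an estimated correlation), with Lhcb1.3 at -4.74 (SE 1.01, from 4.99 ± 0.32, SD, n = 5, to 0.25 ± 2.46, n = 6) and Lhcb6 at -1.17 (SE 0.26). Of 18 Calvin cycle genes 6 fell and 1 rose (9 and 1 over the list alone; median -0.41, adjusted p = 0.00346), with the isomerase cpTPI at -1.15 (SE 0.28). Of 10 chlorophyll synthesis genes 5 fell and 0 rose (5 over the list alone; median -0.73, adjusted p = 0.018, or 0.111 without days 76 and 83), with PORA at -3.10 (SE 0.74). The adjusted p was 0.741 for both with an estimated correlation. With slide as a fixed block the photosystem, Calvin cycle and chlorophyll synthesis medians were -0.06 (adjusted p = 0.569), -0.15 (0.53) and -0.32 (0.53). With quantile normalization the photosystem and Calvin cycle medians were -0.14 and -0.27.

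Single genes of cell walls and of gibberellin synthesis fell between the same windows, though not their lists as wholes. The list of cellulose and lignin genes had 6 of 8 lower and 1 higher (the same over the list alone; median -2.13, or -1.84 at the bounds, adjusted p = 0.0532, or 0.00933 without days 76 and 83), with CESA8 at -2.49 (SE 0.41), CESA4 at least 4.27-fold and BC1 at least 5.19-fold lower, and CAD2 higher by 3.42 (SE 0.41). CPS1 was at least 19.2-fold lower (2 of 6 late arrays) and KAO fell by 1.64 (SE 0.27), among 5 of 10 gibberellin genes lower and 0 higher (5 and 1 over the list alone; median -0.34, adjusted p = 0.0532). Of 5 cell division genes 2 fell (3 over the list alone; median -1.67, or -0.50 at the bounds, adjusted p = 0.0497; adjusted p = 0.392 with an estimated correlation), with CDKB2;1 at least 3.28-fold lower (2 of 6 late arrays). Of 149 cytosolic ribosomal protein genes 29 fell and 0 rose (0 over the list alone; median -0.70, adjusted p = 5.12e-13; adjusted p = 0.741 with an estimated correlation), and the median was -0.48 (adjusted p = 5.43e-14) without days 20 and 76 and -0.27 (adjusted p = 0.00935) without days 76 and 83. With median scaling 14 of these genes fell and 1 rose. The calls of the cell division and floral lists ended with a floor under dim values (adjusted p = 0.114 and 0.0504). CKX2 was at least 8.86-fold higher, DTH8 fell by 2.1 (SE 0.29), OsMADS56 by 0.96 (SE 0.21) and OsMADS50 by 0.89 (SE 0.25), though the last turned to 0.079 with slide as a fixed block.

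Other lists tested did not pass between these windows, and the 2 heat shock genes were too few for a list test. They are given in the same order of members higher and lower, the list alone in brackets, and the median. Photorespiration genes had 0 and 1 (0 and 1), -0.16, and nitrogen genes 1 and 1 (1 and 1), -0.08 with a mean of 0.05. Flowering genes had 1 and 3 (1 and 3), -0.07 with a mean of 0.00912, and clock genes 0 and 0 (0 and 0), -0.08. Sucrose and starch genes had 0 and 1 (0 and 0), 0.10 with a mean of -0.03, phosphate starvation genes 0 and 0 (0 and 0), 0.08, and abscisic acid genes 0 and 2 (0 and 2), -0.42. Cold response genes had 0 and 1 (0 and 1), -0.49, and cytokinin genes 1 and 1 (1 and 1), -0.07 with a mean of 0.31. Heat shock genes had 0 and 0 (0 and 0), 0.34, plastid ribosomal proteins 0 and 0 (0 and 0), -0.36, and histones 7 and 4 (7 and 4), 0.22. The flowering median turned positive, at 0.05, with quantile normalization, and its camera test pointed down.

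In all, 2575 genes were higher and 2878 lower in the late than in the middle window (23.9%), of which 1193 and 1803 differed at least 2-fold. Here too the larger direction turned with the scaling, with 3100 higher and 2487 lower with quantile normalization and 3244 and 2565 with median scaling. Large rises were seen in the VQ-domain gene (at least 178-fold, 2 of 5 middle arrays), a subtilase (Os02g0269600, at least 75.6-fold, 0 of 5), a flavanone 3-hydroxylase (Os04g0662600, at least 33.4-fold, 0 of 5) of flavonoid synthesis, PR1b, and a gene described as cellulose synthase CesA-1 (Os04g0429600, 6.93, SE 0.51). Large falls were seen in an O-methyltransferase (Os10g0118200, at least 124-fold, 2 of 6 late arrays), the methyltransferase Os02g0719600 (at least 70.2-fold), the alpha-expansin OsEXPA2 (Os01g0823100, at least 62.9-fold, 0 of 6), a wall-loosening protein, and the peroxidases Os01g0294700 (at least 50.1-fold) and Os02g0240300 (at least 40.8-fold). With slide as a fixed block 38 genes were higher and 82 lower. That estimate rests on slide 3, with 3 middle arrays and 1 late array, and takes the lone late array to vary like the others. The count of higher genes was 1712 without day 76 and 1424 without days 76 and 83. Of 70 calls on named genes 60 remained with each array left out in turn and 51 without days 76 and 83.

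Of genes called, 648 of 11441, 54 of 2344 and 472 of 5453 in the 3 contrasts were well above background on no array of 1 window. For 2289 other probes of genes called with at least a 2-fold difference, 2235 (97.6%) had the same sign as the probe that stood for the gene. Cytosolic ribosomal protein genes were high on days 76 and 83, by medians of 1.14 and 0.78 over the mean of days 69 and 90, with 148 and 149 of 149 higher. Plastid ones lay 0.998 above that mean on day 76, with 17 of 17 higher, and 0.05 above on day 83. On day 20 the cytosolic ones lay lower than on the mean of days 13 and 27 in 147 of 149, with a median of -1.43, and phosphate starvation genes were 1.45 higher.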

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

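The tests of compression, of array scaling and of the phytoalexin genes against slide, and the count of phytoalexin genes without another probe, were chosen only after the result was seen. The median of each list in each window was searched for a single array far from the others, which chance gives for about 1 in 20 groups, and 6 of 75 groups had one. The cytosolic ribosomal protein list lay at 1.13 on day 20, against 2.15 on the nearest of the other 5 early arrays. The reference genes lay at 2.82 on that day, against 3.90. The plastid ribosomal protein list lay at 3.27 on day 76, against 2.36 on the nearest of the other 4 middle arrays. The others were abscisic acid genes on day 62 (-0.81 against -0.36), histones on day 55 (1.03 against 0.42) and gibberellin genes on day 118 (-2.20 against -2.67). A signal was also present in probes named after microRNAs, of which 41 were well above background on all 17 arrays.

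Photosystem and Calvin cycle genes were lower in late leaves. Compression of bright probes is argued against for members with a mean signal up to 6: of 10000 random lists matched on signal, 10 had a median as low for 13 photosystem genes (list -0.87, matched -0.10) and 5 for 8 Calvin cycle genes (list -1.10, matched -0.11). For members above 6, with 123 and 132 of 10000 such lists, compression cannot be told apart, because the matched genes were less bright than the lists (6.24 against 6.56 and 6.21 against 6.54). A difference between slides as the whole source is argued against by the slopes of the members' mean within slides. These were -0.50 per 28 days (95% interval -0.88 to -0.12) for photosystem and -0.36 (-0.69 to -0.03) for Calvin cycle genes. The slope was negative on each of slides 1 to 4, but for photosystem genes it was -0.04 on slide 3 and -1.25 on slide 4. These slopes were not refitted with arrays left out. No slide holds both early and late arrays, and neither list passed late minus early with slide as a fixed block. Growth stage, which the design gives, and anything else in the field that changed with the date stay open as untested explanations.

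Cytosolic ribosomal protein genes were high on days 76 and 83, by medians of 1.14 and 0.78 over the mean of days 69 and 90. Array scaling is argued against, since with quantile normalization, cyclic loess and median scaling the medians were at least 1.06 on day 76 and 0.695 on day 83, with the lower quartile of the members at 0.573 or above. Probe brightness is argued against for day 76, with 0 of 10000 random lists matched on signal rising as far over the mean of days 69 and 83 (list 0.76, matched -0.09). The median level of the 5 reference genes also stood high on days 76 and 83, at 5.34 and 5.04, against 4.24 on day 69 and 4.33 on day 90. Gene by gene, 2 of the 5 were higher on day 76 than on the mean of days 69 and 83. That mean includes day 83, when the reference median also stood high. The count therefore cannot be set beside the ribosomal values taken against days 69 and 90. The handling of the 2 samples of days 76 and 83 stays open, and no biological explanation was tested.

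Phytoalexin genes were higher in late leaves, though on day 97 their median (-2.52) lay near that of day 83 (-2.89). A slide difference as the whole source is argued against by a slope within slides of 2.65 per 28 days (95% interval 0.96 to 4.33), and of 2.01 (0.45 to 3.57) without day 90, the lowest with any array left out. RNA from panicle or floral organs cannot be told apart. The 7 tested floral markers rose by a median of 0.39 (at most 1.70) on day 90, but most are near background, and 5 of 7 rose in the late window. The other markers of that list of 11 were too dim to be tested. A single deviating probe per gene is argued against for CPS4, KSL7 and KSL4, whose other probes rose by 1 or more in 4 of 4 cases, while 6 of the 9 genes have no other probe to test. Growth stage and anything else in the field that changed with the date stay open as untested explanations.

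Regroupings of the 17 arrays were compared with the real windows. As many genes were called in 1 of 100 groupings, the real one included, for late minus early (11441, highest other 8426). The same held in 1 of 100 for late minus middle (5453, highest other 2768), and in 1 of 100 orders of the days for the season (15794, highest other 42). Neighbouring weeks are alike and the slides follow the days, so a smooth drift of any source would give this outcome. The draws therefore cannot tell growth stage, slide and anything else that changed with the date apart. They are no measure of the error of single calls. For middle minus early 2 of 100 groupings called as many (2344, highest other 5918), a share under 0.05, and a regrouping that calls more than the real one points to a structure of the samples, whose source was not tested. Slide as a factor of 5 levels called 10920 genes, while position on the slide called 0 by limma (39 at an unadjusted p under 0.05). The correlation within slides was 0.107 in the window fit and -0.0034 in the season fit.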

How the results depend on the processing

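Cyclic loess and the fits without days 20 and 76 or 76 and 83 were chosen after seeing the data. Each stage has 1 array, windows stand in for replicates, and slide is tied to day. No paired analysis was possible because no label pairs the samples. Genes whose probes were well above background on fewer than 5 arrays were not tested. The counts for the season and for late minus early stayed within 1.5 times under all alternatives but those with slide as a fixed block. With slide as a fixed block 1371 genes changed over the season. The counts of higher and lower genes were 7 and 34 for late minus early, 0 and 0 for middle minus early (limma, 288 at an unadjusted p under 0.05) and 38 and 82 for late minus middle. The block takes up any difference between slides along with most of the difference between days. Which of them the lost calls rested on cannot be told apart. Most of the lower genes called with the block, in late minus early and in late minus middle, were not among those called without it. A straight line with that block called 0 and 0 (limma; 3351 unadjusted).

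Middle minus early gave 118 and 163 genes with slide as a random block, 1720 higher with windows 1 week earlier, 3016 and 3290 with windows 1 week later, 2177 lower with every probe, 18 and 10 without days 20 and 76, and 16 and 6 without days 76 and 83. Late minus middle gave 1917 lower genes with only probes well above background on all 17 arrays, where fewer genes are tested, and 1769 with windows 1 week later, and 1424 higher without days 76 and 83. Leaving out each array gave 156 (day 69) to 2369 (day 55) higher and 207 (day 76) to 2559 (day 55) lower genes for middle minus early, outside 1.5 times also without days 20 (310 and 433), 27 (289 and 411), 48 (2020 and 2343), 62 (340 and 659) and 83 (231 and 317). It gave 1712 (day 76) to 3126 higher for late minus middle. The cause was not tested.

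Lists called were 6, 5 and 8 in late minus early, middle minus early and late minus middle. They were 0 in each with an estimated correlation, 11 and 8 in the first 2 with every probe, 13 in the first with fry, 1 in the second with quantile normalization, 1 with the slide block and 8 with windows 1 week earlier. In the third they were 5 with the matrix values, the 17-array filter, the floor and the slide block, and 5 to 10 with each array left out, with 5 without days 13, 34, 48, 62, 69, 111, 118 or 125; the cause was not tested.

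With slide as a fixed block the median of the defence list in late minus middle changed sign (0.72). Without the block its median was -0.146, but its mean was 0.485 and camera pointed up. MADS50 (0.079) and SGR (-0.001051) also changed sign in that contrast. In late minus early MADS18 (-0.29), COL4 (0.017), PHYA (-0.018), SE5 (0.051) and PRR59 (0.27) did so. The same held for FKF1 (0.20), SPX2 (0.91), SPX1 (0.98), PCNA (-0.29) and Os06g0308200 (-0.089). The blocked late minus early estimates compare fewer days than the windows do, so these are not reversals of the same comparison. The cause was not tested.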

Other observations

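The microRNA probes and the gene families below were chosen after seeing the data. The array carries 510 distinct probes for microRNAs and their precursors, of which 135 were well above background on at least 5 arrays. Between late and early leaves 14 were higher and 70 lower, and 99 changed over the season. For miR169, whose known targets are NF-YA factors, 21 of 22 probes were lower in the late and 19 in the middle window. The miR169h and miR169i probes for the 3' flanking sequence were well above background on 6 of 6 early, 0 of 5 middle and 0 of 6 late arrays, and the miR169e probe for the 5' flanking sequence, measured on all 17, fell by 0.96 (SE 0.25, adjusted p = 0.00379). For miR166, which targets HD-ZIP III factors, 15 of 17 probes were lower in late leaves and 0 differed in the middle window. All 11 miR439 probes were higher in late leaves, and the miR439a probe for the 3' flanking sequence was well above background on 0 of 6 early, 0 of 5 middle and 6 of 6 late arrays. The miR398a probe for the 3' flanking sequence, from a family that targets copper/zinc superoxide dismutases, was well above background on 5 of 6 early, 0 of 5 middle and 6 of 6 late arrays. The miR398b probe for the 5' flanking sequence went the other way in the middle window (2 of 6 early and 5 of 5 middle arrays, adjusted p = 0.0309). For miR168, which targets AGO1, 3 of 3 probes were lower in late leaves (miR168a, 3' flanking sequence, -0.58, SE 0.13). The counts mix probes for flanking sequences with probes for mature sequences, which were 25 of the 135, with 9 of 17 for miR166, 1 of 3 for miR168, 2 of 6 for miR398 and 0 for miR169 and miR439. Which form of the RNA a probe detects was not tested.

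Of 15 gene families by description, 11 passed between early and late leaves and 4 did not, namely aquaporins (camera adjusted p = 0.86), chitinases and glucanases (0.912), terpene synthases (0.396) and autophagy and vacuolar proteases (0.876). WRKY factors (31 of 61 higher, 12 lower, median 0.83, camera adjusted p = 0.00176) and disease resistance genes (87 of 184 higher, 32 lower, 0.54, 1.24e-04) rose as families. Expansins (15 of 21 lower, 0 higher, -1.43, 2.82e-04), lipid transfer proteins (10 of 18 lower, 0 higher, -1.47, 0.00164) and kinesins and tubulins (28 of 55 lower, 3 higher, -0.68, 0.00153), which serve wall loosening, surface lipids and the cytoskeleton, fell. With an estimated correlation the adjusted p was 0.365 for each of the 5. Heat shock proteins by description (median 0.35), NAC factors (0.56), cytochromes P450 (0.50) and glutathione S-transferases (0.37) also passed as higher, and peroxidases (-1.85) and xyloglucan transferases (-3.34, 3 members) as lower. None of these 6 passed with an estimated correlation (adjusted p from 0.365 to 0.392).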
